A study of Homo sapiens with 8 samples.

How the data were processed

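RNA sequencing libraries from 2 human acute myeloid leukaemia cell lines, HL60 and Kasumi-1, were compared with and without 100 nM cinobufagin for 24 h. Each of the 4 groups held 2 libraries, numbered 1 and 2 in the labels. Per the labels' protocols, total RNA was collected with an RNeasy kit and libraries were made with a TruSeq Stranded mRNA kit, which selects RNA by its poly(A) tail. HL60 was grown with a lower share of fetal bovine serum than Kasumi-1, so the serum and the cell line cannot be separated in any comparison between the lines.

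The authors deposited 1 table of FPKM values (fragments scaled to transcript length and to the mapped fragments of the library), with a column per library and 25593 gene rows. Per the submitters' processing notes, the tools were bcl2fastq 2.20.0, HISAT2 2.1.0 and Cufflinks 2.2.1, and the genome build was hg19. The labels name a kit that keeps strand. The gene annotation, the strand setting of the quantification and any filter are not given in the sources used here, so antisense and overlapping genes could not be told apart with certainty. All 8 columns were used and 0 were left out. Read totals are not given in the sources used here. A relative depth was taken from genes with FPKM under 0.3 in all libraries, as the inverse of the most frequent ratio of their values to those of untreated HL60 replicate 1 (1004 to 1238 genes). It lay between 0.79, in treated Kasumi-1 replicate 1, and 1.06, in untreated Kasumi-1 replicate 2. Gene lengths are not given in the sources used here, so whole reads were not recovered and no count model was fitted. Without counts, no counting interval could be set on a value, and an FPKM listed at 0 was not read as absence.

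From these values, log2(FPKM + 1) was computed and tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 8 libraries, which leaves 4 residual degrees of freedom, and variances were moderated with an intensity trend. Genes with FPKM of at least 1 in at least 2 of the 8 libraries were tested, 12511 in all, and 13082 were not. The contrasts were cinobufagin against untreated in each line, and the difference between those changes (Kasumi-1 minus HL60). P-values were adjusted by Benjamini-Hochberg over the genes of each contrast, and an adjusted p under 0.05 is called a change. A log2 change on the log2(FPKM + 1) scale understates the change of genes with low values. A permutation of 2 against 2 libraries cannot give a two-sided p below 0.33, so no such test was used.

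Before the data were examined, 37 gene lists were written from textbook knowledge, covering the MYC network and MYC targets, growth and cell cycle, stress responses, inflammation, metabolism, myeloid differentiation, ion transport and markers of other cell types. Of 1022 list entries, 1008 had a row. The 31 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 31 lists. Camera with an estimated correlation, and limma's fry, were alternatives. For some lists the estimate lay below the preset, yet camera's p-value rose. In HL60 it was −0.011 for nucleolar MYC targets (camera adjusted p from 7.57e-11 to 0.03) and −0.009 for the BCL2 family (from 0.0014 to 0.0566). A call lost under this alternative is therefore not by itself a sign that the members are correlated. Fry asks whether the members move, on balance, in a single direction, without comparing them with other genes. Counts of changed members are given over all genes and adjusted over the list alone.

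Genes were named by a rule fixed before the data were examined. For each line these are the 8 genes per direction with the largest log2 change among those with an adjusted p under 0.05, a mean FPKM of at least 5 in the higher group and both treated libraries beyond both untreated ones. Symbols that start with LOC, MIR, SNOR, SCARNA, RNU, LINC or RN7S and symbols with more than 1 row were left out. Further named genes are the 8 per direction that passed in both lines, ranked by the smaller log2 change, the 6 per direction with the largest difference between lines, and the 4 members with the smallest adjusted p of each list called in a line. For other lists up to 2 changed members per direction were named. MYC, MAX, MXD1, MCL1, BCL2, CDKN1A, ATP1B1, ATP1B3 and a list of genes that identify the lines were always included. Some genes that the rule names are not reported here. The 5S RNA copies that the rule picked take up part of the places for the largest rises, so the next genes in rank (IL8, CCL2, IER3 and RGS2 in HL60, and IL8, S100A4 and PIWIL4 in Kasumi-1) were added after their values were seen. The gene families that open the other observations were also chosen after the values were seen.

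Alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, a filter at FPKM of at least 5, rescaling of libraries by the median ratio to the geometric mean, quantile normalization, a fit on each line alone, no intensity trend, a replicate block within each line, a minimum change of 1.5-fold (limma's treat) and leaving out each library in turn. Where a library was left out, the lone sample of its group was assumed to vary like the other groups. Alternatives added after the data were seen were the replicate number as a single term over both lines, and tests without rows of short RNAs and repeated symbols.

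For checks on transcript length and 3' UTR features, gene symbols were matched to GENCODE v29, an annotation of GRCh38. Its build differs from that of the authors, so no coordinates from it are used. Of the tested genes, 11166 had a match. Random sets in these checks were drawn 10000 times with fixed seeds.

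The tests were checked on simulated data made from the means and spreads of the tested genes (12511), with 200 genes changed by known amounts, 50 at each size. The changed genes were drawn from those with a mean log2(FPKM + 1) above 1, so recovery of lower genes was not tested. In the HL60 simulation, 52% of genes changed by 0.4 on the log2 scale were recovered, 84% at 0.8, 96% at 1.6 and 98% at 3.2, and 4.3% of the calls were false. In the Kasumi-1 simulation the shares were 30%, 88%, 98% and 98%, with 1.1% of the calls false. Both simulations used the same spreads, shared over the 4 groups, and separate random draws, so their shares do not describe a difference between the lines. A fall of 0.4 planted in the mitochondrial ribosome list was called in both simulations, and 0 of the 30 other lists were called. Noise was drawn for each gene on its own, so false list calls under correlation between genes were not tested. In the data, the estimated correlation reached 0.814 for ribosomal proteins. A far larger share of genes changed in HL60 (73.6%) than in the simulation. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.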

Results

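Gene expression was measured in HL60 and Kasumi-1 cells, each cultured for 24 h without drug or with 100 nM cinobufagin, a bufadienolide of toad venom that binds the Na+/K+-ATPase as cardiac glycosides do. HL60 is a promyelocytic leukaemia line with an amplified MYC gene, and Kasumi-1 is a myeloblastic line that carries the RUNX1-RUNX1T1 fusion. The 8 libraries formed 4 groups of 2, and all means below are FPKM ± SD over the 2 libraries of a group. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Between 10623 and 11371 genes per library reached an FPKM of 1, and relative depth ranged from 0.79 to 1.06. Replicates of a group correlated with Pearson's r between 0.967 and 0.974 across genes, and replicates of a group shared at most 2 nonzero values.

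The lines matched their labels. MYC stood at 768 ± 26 FPKM in untreated HL60 and at 309 ± 1.5 in untreated Kasumi-1. RUNX1T1 was listed at 0 in all 4 HL60 libraries and stood at 19.1 ± 2.4 in untreated Kasumi-1. CD34 and TRH were listed at 0 in all HL60 libraries, against 59.8 ± 1.9 and 89.0 ± 2.1 FPKM in untreated Kasumi-1, and KIT stood at 0.846 ± 0.21 against 152 ± 9.5. POU4F1 was low in both lines, with untreated means of 0.435 ± 0.084 FPKM in HL60 and 0.215 ± 0.036 in Kasumi-1. Markers of other cell types were mostly near 0. Only 4 of 21 erythroid and megakaryocyte genes passed the filter on low values (highest group mean 7.46 FPKM, EPOR), 2 of 15 T and NK cell genes (93.0, NKG7), 3 of 10 B cell genes (13.6, CD79B) and 1 of 16 fibroblast and epithelial genes (77.9, EPCAM). The 13 mitochondrially encoded mRNAs had no rows and were not analysed here.

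The replicate numbers separated the libraries in part of the table. SNORD50A, a short nucleolar RNA, was listed at 0 in each replicate 1 library and between 45596 and 748781 FPKM in each replicate 2 library. Changes were therefore also taken within each number. Across tested genes, which are not independent replicates, the changes of replicate 1 and replicate 2 correlated with Pearson's r of 0.86 in HL60 and 0.39 in Kasumi-1, and of 0.98 and 0.78 without short RNAs and repeated symbols.

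The first comparison asked how cinobufagin changed the transcriptome of HL60, and the series title names genes of the c-Myc pathway. MYC, a transcription factor that drives ribosome production and growth, fell from 768 ± 26 to 29.8 ± 0.75 FPKM, a log2 change of −4.64 (SE 0.05, limma adjusted p = 7.85e-08). The change was −4.65 within replicate 1 and −4.63 within replicate 2. Together with MYC, 51 of 59 mostly nucleolar MYC targets fell, as did all 23 tested genes of cholesterol synthesis and uptake. Inflammatory chemokines, immediate early transcription factors and mitotic genes rose, and CCL3 went from 0.468 ± 0.14 to 218 ± 4.4 FPKM. In all, 4505 genes rose and 4707 fell (limma, Benjamini-Hochberg), 73.6% of the 12511 tested, and 1484 and 1763 of these changed at least 2-fold. FPKM is scaled within each library, so rises and falls here and below are relative to the other genes. A change in total mRNA per cell would not be seen in these values.

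**Figure D1:**
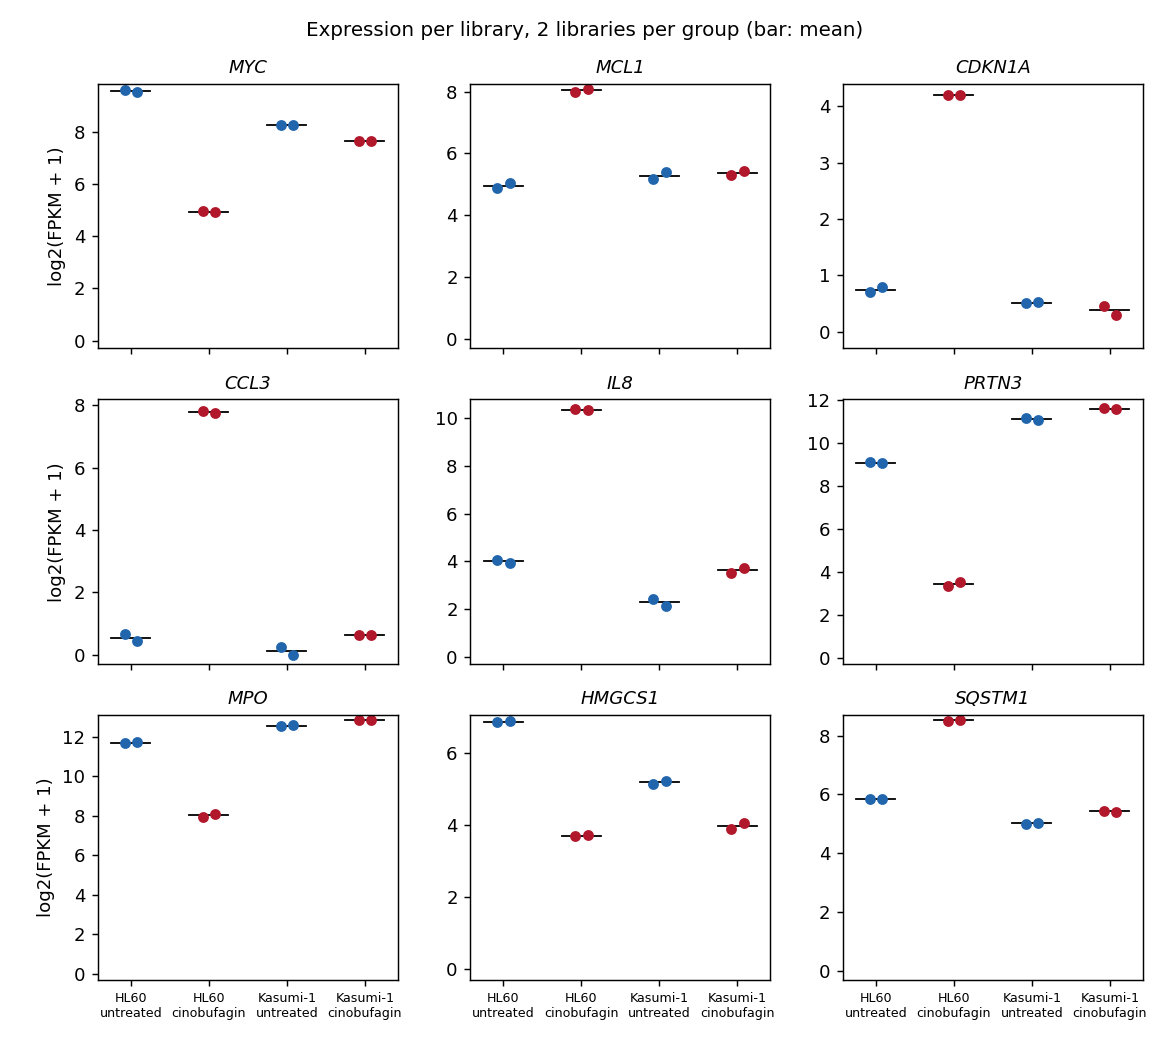
Expression of 9 named genes as log2(FPKM + 1) in each of the 8 libraries, with untreated libraries in blue, cinobufagin in red and a bar at the mean of each group of 2. MYC lies at 29.8 FPKM in treated HL60 against 201 in treated Kasumi-1, and MCL1, CDKN1A, CCL3 and IL8 are highest in treated HL60.

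MYC targets fell in 2 separate lists. In the mostly nucleolar list, 51 members fell and 4 rose (52 fell and 4 rose when adjusted over the list alone), with a median log2 change of −1.19 (camera adjusted p = 7.57e-11, and 0.03 with an estimated correlation). SLC29A2, a nucleoside transporter, fell from 37.0 ± 1.9 to 0.743 ± 0.2 FPKM, SORD fell by 3.78 on the log2 scale, and RRP9, a factor of pre-rRNA processing, fell by 2.87. In the list of MYC targets outside the nucleolus, 38 of 46 fell and 5 rose, also when adjusted over the list alone (median −0.81, camera adjusted p = 3.89e-06, and adjusted p = 0.0451 with an estimated correlation). IMPDH2, which makes guanine nucleotides, fell from 234 ± 5.2 to 23.8 ± 0.33 FPKM, CAD, which starts pyrimidine synthesis, from 39.7 ± 1.9 to 5.22 ± 0.1, and ODC1, of polyamine synthesis, from 180 ± 1.9 to 41.8 ± 0.44. Of the 11 tested transcription factors of the MYC network, 7 rose and 2 fell (the same counts adjusted over the list alone), among them MXD1, an antagonist of MYC, at +1.08, and its dimer partner MAX, at −0.21 (SE 0.07, adjusted p = 0.0274). The call for MAX was lost without any of the 4 HL60 libraries (adjusted p between 0.0603 and 0.12). The network list as a whole was not called (camera adjusted p = 0.249), and its median, 0.36, and its mean, −0.02, differed in sign.

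Most genes of the cytosolic ribosome, the mitochondrial ribosome and the respiratory chain also fell. Of 78 cytosolic ribosomal protein genes 67 fell and 0 rose (the same adjusted over the list alone), with a median of −0.63 (camera adjusted p = 9.56e-09, but adjusted p = 0.579 with an estimated correlation). RPL12 fell from 3490 ± 250 to 727 ± 40 FPKM and RPS2 from 3890 ± 67 to 1040 ± 60, and the list's share of the FPKM of tested genes other than short RNAs went from 39.1% and 37.5% in the untreated libraries to 27.7% in both treated ones. The fall was −0.70 within replicate 1 and −0.59 within replicate 2, and it shrank to −0.15 under quantile normalization (adjusted p = 0.0579). Mitochondrial ribosomal proteins fell in 29 of 40 cases and rose in 5 (median −0.70, camera adjusted p = 0.000232, and adjusted p = 0.437 with an estimated correlation), with the same counts adjusted over the list alone. MRPL24 fell from 68.3 ± 0.38 to 5.57 ± 1.1 FPKM. Respiratory chain and ATP synthase subunits fell in 25 of 43 cases and rose in 5, over all genes and adjusted over the list alone (median −0.34, adjusted p = 0.00835, and adjusted p = 0.609 with an estimated correlation), for example NDUFV1, which fell by 1.92 on the log2 scale.

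Cholesterol synthesis and granule genes fell as well. All 23 tested members of the cholesterol list fell, also when adjusted over the list alone (median −1.71, camera adjusted p = 4.26e-09, and adjusted p = 0.0566 with an estimated correlation). DHCR7, the last enzyme of the pathway, fell from 64.9 ± 3.4 to 2.06 ± 0.37 FPKM and HMGCS1, an early one, from 115 ± 2.5 to 12 ± 0.24. Of 13 primary granule genes, which mark promyelocytes, 11 fell and 1 rose, over all genes and over the list alone (median −2.48, camera adjusted p = 0.000333, and adjusted p = 0.301 with an estimated correlation). PRTN3, which encodes proteinase 3, went from 539 ± 12 to 9.77 ± 1 FPKM, MPO, which encodes myeloperoxidase, from 3330 ± 59 to 260 ± 21, and ELANE, which encodes neutrophil elastase, from 206 ± 4.2 to 26.4 ± 1.4. Stem and progenitor genes fell in 11 of 19 cases and rose in 3 (median −0.52, adjusted p = 0.0355, and adjusted p = 0.193 with an estimated correlation), with the same counts adjusted over the list alone, among them CEBPA at −2.15, WT1 at −2.24 and FLT3 at −1.93. Other genes with the largest falls were IGLL1, part of the surrogate light chain of B cell precursors (−6.56), GAL, which encodes the neuropeptide galanin (−4.99), MZB1 (−4.92) and UCP2, a mitochondrial carrier (−4.55).

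Inflammatory genes rose most. In the NF-kB and inflammatory list, 24 of 25 tested genes rose and 0 fell, over all genes and adjusted over the list alone, with a median of 3.08 (camera adjusted p = 3.09e-10, and 0.0373 with an estimated correlation). The chemokine gene CCL4 rose from 1.88 ± 0.88 to 596 ± 31 FPKM and CCL3 by 7.23 on the log2 scale. CCL4L1 and CCL4L2 are near-identical copies of CCL4, and their values (195 ± 14 and 196 ± 13 FPKM in treated cells) are uncertain because the copies share reads, as is that of CCL3, which has near-identical copies too. Among the genes next in rank, IL8, which encodes the neutrophil chemoattractant CXCL8, rose from 15.1 ± 1.1 to 1310 ± 25 FPKM and CCL2 from 11 ± 0.58 to 788 ± 82. IL1RN, NFKB2 and RELB rose by 4.37, 3.65 and 3.62. Immediate early genes rose in 29 of 31 cases, over all genes and over the list alone, and 0 fell (median 2.54, camera adjusted p = 1.92e-11, and 0.0373 with an estimated correlation), with EGR2, FOSB, JUN and MAFF at 4.01, 4.47, 3.44 and 3.50. IER3 and RGS2, next in rank as well, rose by 6.03 and 5.56.

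Genes of mature myeloid cells, lysosomes and mitosis rose too. Of 33 genes of maturing granulocytes and monocytes 28 rose and 3 fell, or 28 and 5 adjusted over the list alone (median 1.30, camera adjusted p = 1.06e-06, and 0.0373 with an estimated correlation). CD14, a monocyte receptor, rose from 2.71 ± 0.35 to 38.5 ± 0.94 FPKM, and the formyl peptide receptors FPR1 and FPR2 rose by 3.26 and 2.97. NKG7, a marker of T and NK cells, also stood higher, at 97.7 and 88.4 FPKM in the treated libraries against 25.2 and 26.3. Lysosome and autophagy genes rose in 29 of 31 cases (median 1.12, camera adjusted p = 7.8e-09, and 0.0394 with an estimated correlation). None fell over all genes and 1 fell when adjusted over the list alone, where 29 rose. SQSTM1, an autophagy receptor, rose from 56.0 ± 0.19 to 365 ± 2.6 FPKM. G2 and mitosis genes rose in 35 of 36 cases, over all genes and over the list alone (median 1.06, camera adjusted p = 6.82e-10, and 0.0373 with an estimated correlation), for example NDC80, a kinetochore protein, from 20.6 ± 0.072 to 110 ± 7.6. Of 17 CDK inhibitors, cyclins and other cell cycle regulators 13 rose and 3 fell, over all genes and over the list alone (median 1.25, camera adjusted p = 0.00451, and adjusted p = 0.0773 with an estimated correlation). CDKN1A, the CDK inhibitor p21, rose from 0.675 ± 0.082 to 17.5 ± 0.0067 FPKM, the cyclin gene CCND3 from 31.2 ± 1.1 to 282 ± 16 and BTG2 from 3.48 ± 0.18 to 87.2 ± 0.3. CDKN2A rose from 8.85 ± 1 to 32.6 ± 3.6.

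Replication-dependent histone genes rose in 16 of 19 cases, over all genes and over the list alone, and 0 fell (median 1.69, camera adjusted p = 3.32e-05, and 0.0394 with an estimated correlation). HIST1H2BK rose from 27.1 ± 0.66 to 305 ± 7.5 FPKM. Most histone mRNAs of this kind lack a poly(A) tail, though the values do not show whether the histone transcripts measured here had one. RNAs without a tail stood higher in the same libraries. RN7SK, the 7SK RNA, rose from 16.0 ± 4.8 to 116 ± 19 FPKM, and copies of 5S ribosomal RNA were among the largest rises. RN5S14, RN5S6, RN5S15 and RN5S17 were listed at 0 in both untreated libraries and averaged 83.7 to 89.9 FPKM in treated ones. These copies share reads, so each value is uncertain.

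Survival and stress genes moved in both directions. Of 23 genes of the BCL2 family and caspase regulators 17 rose and 3 fell, or 18 and 3 adjusted over the list alone (median 0.63, camera adjusted p = 0.0014, and adjusted p = 0.0566 with an estimated correlation). The antiapoptotic MCL1 rose from 30.1 ± 2.5 to 262 ± 15 FPKM and BCL2A1 by 3.51, the proapoptotic BMF rose by 2.55, and BCL2 fell from 19.1 ± 0.37 to 8.08 ± 1.3 FPKM (−1.15, SE 0.14, adjusted p = 0.000324). ATF4 and CHOP targets of the integrated stress response rose in 20 of 25 cases and fell in 4, over all genes and over the list alone (median 0.53, adjusted p = 0.00172, and adjusted p = 0.0566 with an estimated correlation). PPP1R15A, which restores translation after stress, rose by 3.92. Other ion transport genes rose in 15 of 28 cases and fell in 7, over all genes and over the list alone (median 0.53, adjusted p = 0.0439, and adjusted p = 0.765 with an estimated correlation), led by the kinase SGK1 at 4.22. That call ended without HL60 untreated replicate 1 (adjusted p = 0.0583), HL60 treated replicate 2 (0.0584), Kasumi-1 treated replicate 1 (0.0526) or Kasumi-1 treated replicate 2 (0.0527). It also ended with a pseudocount of 0.1 (adjusted p = 0.055), a filter at FPKM of at least 5 (0.092) and HL60 fitted alone (0.0576). Of the Na+/K+-ATPase genes only 4 were tested. The beta subunit genes ATP1B1 and ATP1B3 rose by 1.21 and 1.44, and the regulator FXYD5 fell by 0.38.

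The remaining lists were not called in HL60. Heat shock proteins had 4 rises and 9 falls among 19 (camera adjusted p = 0.112), with HSP90AB1 falling from 637 ± 0.19 to 159 ± 0.82 FPKM. ER chaperones had 11 rises and 10 falls among 24 (adjusted p = 0.978), with CALR at −1.83 and EDEM1 at +1.64, a median of 0.08 and a mean of −0.12. NRF2 targets had 9 and 7 among 18 (0.464), led by the heme oxygenase gene HMOX1 at 4.17 and FTH1 at 3.26. Genes induced by p53 had 9 and 4 among 20 (0.138), with TNFRSF10B at 2.69. DNA replication genes had 11 rises and 23 falls among 40 (0.188), with POLD2 at −1.60. Glycolysis and hypoxia genes had 12 and 10 among 26 (0.391), with SLC2A3 at 3.63 and PFKP at −1.97. Antigen presentation had 7 and 6 among 14 (0.727), interferon genes 7 and 5 among 17 (0.727), proteasome subunits 8 and 14 among 31 (0.664), tRNA synthetases 8 and 10 among 19 (0.664), splicing factors 13 and 14 among 37 (0.978), and the genes that identify the lines 2 and 3 among 8 (0.671). Adjusted over the list alone, these counts became 11 and 24 for DNA replication and 13 and 10 for glycolysis and hypoxia, and were the same for the other 10. Splicing factors, with a median of 0.01 and a mean of 0.00, were placed lower by camera, as were ER chaperones. Quantile normalization gave a call to heat shock proteins (adjusted p = 0.0424), and leaving out the filter on low values one to p53 targets (0.0403).

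The second comparison asked the same of Kasumi-1, in which changes were smaller. MYC fell from 309 ± 1.5 to 201 ± 2.2 FPKM, a log2 change of −0.62 (SE 0.05, limma adjusted p = 0.00124), or −0.63 within replicate 1 and −0.62 within replicate 2. Nucleolar MYC targets fell in 49 of 59 cases, and cholesterol genes in 17 of 23 (adjusted p = 0.0171 and 0.0635 with an estimated correlation). Lysosome and autophagy genes rose in 14 of 31 cases and primary granule genes in 8 of 13, against 11 falls among these 13 in HL60 (adjusted p = 0.0517 and 0.28 in Kasumi-1 with an estimated correlation). In all, 1266 genes rose and 2026 fell (limma, Benjamini-Hochberg), 26.3% of those tested, and 40 and 32 of these changed at least 2-fold.

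Most of these calls were small changes, with a median absolute log2 change of 0.39 against 0.78 for the calls in HL60. The split of 38.5% rises among the calls became 51.7% after rescaling by median ratios and 48.3% after quantile normalization. The first rescaling moved the median log2 change of all genes from −0.04 to 0.00. Without untreated Kasumi-1 replicate 1 there were 656 rises and 1052 falls, without untreated replicate 2 635 and 1019, without treated replicate 1 651 and 1136, and without treated replicate 2 741 and 1314.

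Nucleolar MYC targets had a median of −0.41, with 49 falls and 1 rise over all genes and 51 and 2 adjusted over the list alone (camera adjusted p = 4.29e-14). This was the only Kasumi-1 list still called with an estimated correlation (adjusted p = 0.0171). NCL, which encodes nucleolin, fell from 296 ± 11 to 193 ± 2.5 FPKM, MRTO4 fell by 0.77 and NOLC1 fell by 0.51. The MYC targets outside the nucleolus fell in 31 of 46 cases, or 34 adjusted over the list alone, and 0 rose (median −0.37, camera adjusted p = 1.28e-10, and adjusted p = 0.0517 with an estimated correlation). TERT, the catalytic subunit of telomerase, fell from 4.63 ± 0.13 to 2.08 ± 0.06 FPKM and PAICS, of purine synthesis, from 301 ± 15 to 170 ± 6.2. MXD3, of the MYC network, rose from 10.2 ± 0.09 to 22.6 ± 2.3. MXD1 stood at +0.35 (adjusted p = 0.0319), a call lost without any of the 4 Kasumi-1 libraries or either treated HL60 library (adjusted p between 0.0542 and 0.131). MAX stood at −0.05 (adjusted p = 0.624). The network list held 2 rises and 3 falls among 11, also over the list alone (camera adjusted p = 0.988).

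Sterol, heat shock and proteasome genes were among those that fell. Cholesterol genes had 17 falls and 0 rises among 23, or 19 falls adjusted over the list alone (median −0.47, camera adjusted p = 9.15e-10, and adjusted p = 0.0635 with an estimated correlation). HMGCS1 fell from 35.2 ± 1.3 to 14.6 ± 1.1 FPKM and CYP51A1 from 26.6 ± 2.1 to 12.1 ± 2.1. Heat shock proteins fell in 13 of 19 cases, over all genes and over the list alone, and 0 rose (median −0.36, camera adjusted p = 4.14e-06, and adjusted p = 0.0517 with an estimated correlation), among them HSP90AA1 from 602 ± 4.5 to 326 ± 9.5 FPKM and HSPA8 from 984 ± 3.4 to 599 ± 15. Proteasome subunits fell in 19 of 31 cases, or 26 adjusted over the list alone (median −0.24, camera adjusted p = 1.18e-07, and adjusted p = 0.188 with an estimated correlation), with PSMD1 at −0.75. DNA replication genes fell in 20 of 40 cases and rose in 3, or 20 and 4 over the list alone (median −0.23, adjusted p = 0.000509, and adjusted p = 0.0615 with an estimated correlation), with RRM2, of deoxynucleotide synthesis, at −0.78. Mitochondrial ribosomal proteins fell in 19 of 40 cases, or 24 over the list alone (median −0.26, adjusted p = 3.66e-05, and adjusted p = 0.384 with an estimated correlation), tRNA synthetases in 11 of 19, or 15 over the list alone (median −0.22, adjusted p = 4.07e-05, and adjusted p = 0.132 with an estimated correlation), and splicing factors in 17 of 37, with 5 rises, or 20 and 6 over the list alone (median −0.15, adjusted p = 0.021, and adjusted p = 0.336 with an estimated correlation). MRPL3 fell by 0.52, FARSB fell by 0.55 and SRSF7 fell by 0.56. The splicing call ended without treated Kasumi-1 replicate 2 (adjusted p = 0.0699).

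Among rising groups, lysosome and autophagy genes had 14 rises and 0 falls among 31, or 18 rises adjusted over the list alone (median 0.22, camera adjusted p = 5.69e-10, and adjusted p = 0.0517 with an estimated correlation). CTSB, which encodes cathepsin B, rose from 17.8 ± 0.55 to 34.0 ± 0.67 FPKM and GLA from 50.6 ± 2.4 to 100 ± 7.4. Primary granule genes rose in 8 of 13 cases and 0 fell, or 9 over the list alone (median 0.49, adjusted p = 2.71e-05, and adjusted p = 0.28 with an estimated correlation), with PRTN3 going from 2200 ± 83 to 3100 ± 70 FPKM and the proteoglycan gene SRGN from 47.3 ± 2.7 to 88.8 ± 1.6. Mitosis genes had 12 rises and 1 fall among 36, or 16 and 1 over the list alone (median 0.19, adjusted p = 4.78e-07, and adjusted p = 0.0615 with an estimated correlation), with NDC80 at +0.41 and PBK at −0.52. Histone genes had 6 rises and 0 falls among 19, or 7 and 1 over the list alone (median 0.38, adjusted p = 0.000509, and adjusted p = 0.0635 with an estimated correlation). HIST1H2BK rose from 7.96 ± 0.52 to 25.2 ± 0.56 FPKM, while the 7SK RNA stood at 59.3 and 41.9 FPKM in the treated libraries against 11.8 and 24.5. Antigen presentation genes rose in 8 of 14 cases and fell in 2, over all genes and over the list alone (median 0.38, adjusted p = 0.016, and adjusted p = 0.269 with an estimated correlation), a call that ended without untreated Kasumi-1 replicate 2 (adjusted p = 0.0804). HLA-B and HLA-E rose by 0.46 and 0.41, and PSMB8 fell by 0.58.

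For 3 further lists that camera called higher, the medians were near 0. Of 78 ribosomal protein genes 0 rose and 0 fell in Kasumi-1 by limma, over all genes, adjusted over the list alone and at an unadjusted p under 0.05 (median 0.08, camera adjusted p = 0.00513, and adjusted p = 0.821 with an estimated correlation). The list's call ended without untreated Kasumi-1 replicate 2 (adjusted p = 0.681) or treated replicate 1 (0.86), and quantile normalization turned its median to −0.03. Immediate early genes had 8 rises and 3 falls among 31, or 9 and 3 over the list alone (median 0.01, adjusted p = 0.037, and adjusted p = 0.31 with an estimated correlation), with KLF10 at +1.05, JUN at +0.69, DUSP4 at −0.83 and DUSP6 at −0.72. NF-kB genes had 8 rises and 3 falls among 25, over all genes and over the list alone (median 0.02, adjusted p = 0.0441, and adjusted p = 0.285 with an estimated correlation). IL8 rose by 1.34 and NFKBIA by 0.56, and SOD2 fell by 0.56. The NF-kB list's median level in Kasumi-1 was 0.771 FPKM untreated and 0.541 treated, where the log2(FPKM + 1) scale understates a change. The immediate early call ended without untreated Kasumi-1 replicate 1 (adjusted p = 0.0644), and the NF-kB call without untreated replicate 2 (0.125), treated replicate 1 (0.0812) or treated replicate 2 (0.0535). Rescaling by median ratios and quantile normalization ended both calls (adjusted p = 0.0812 and 0.0505 for immediate early genes, and 0.113 and 0.0799 for NF-kB genes), and a filter at FPKM of at least 5 ended the NF-kB call (0.0605).

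By the naming rule and apart from short RNAs, the largest single rise in Kasumi-1 was that of CD82, a tetraspanin, from 3.31 ± 0.19 to 15.3 ± 1.3 FPKM. It was followed by CRIP1 (1.84), HIST1H2BK (1.55), MFAP4 (1.41) and SAT1, a polyamine-degrading enzyme (1.39). IL8 and S100A4 (both 1.34) and PIWIL4 (1.32) were next in rank. The 5S RNA copies RN5S4, RN5S6 and RN5S16 stood at +2.41, +1.92 and +1.54 with shared reads, and the call for RN5S4 was lost without 5 of the 8 libraries and that for RN5S6 without 7 (adjusted p between 0.0516 and 0.181). The largest falls were those of PRG2, an eosinophil granule protein (−1.71), the metallothionein genes MT1G (−1.46) and MT1E (−1.41), UCP2 (−1.35) and ELOVL6, which elongates fatty acids (−1.26). The call for MT1G ended without untreated Kasumi-1 replicate 1 (adjusted p = 0.0523), and that for MT1E without either untreated library (0.0501 and 0.0505) or treated replicate 2 (0.0511). MCL1 stood at +0.09 (adjusted p = 0.574), CDKN1A at −0.14 (0.246), BCL2 at +0.16 (0.439) and ATP1B1 at +0.21 (0.13). ATP1B3 rose by 0.40 and FXYD5 by 0.37. CD34 fell by 0.44, TRH rose by 0.67, and RUNX1T1 and KIT stood at −0.10 and −0.13 (0.543 and 0.366).

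The other lists were not called in Kasumi-1. Maturing myeloid genes had 9 rises and 5 falls among 33 (camera adjusted p = 0.0742), with CD68 at +0.96 and FPR2 at −0.54. Stress response genes had 4 rises and 10 falls among 25 (0.356), with PPP1R15A at +0.94 and CBS at −0.82. NRF2 targets had 3 and 7 among 18 (0.335), with FTH1 at +0.83 and NQO1 at −1.08. Glycolysis and hypoxia had 2 and 6 among 26 (0.0733), interferon genes 3 and 5 among 17 (0.601), with IFIT1 at −1.18, BCL2 family genes 2 and 3 among 23 (0.603), CDK inhibitors and cyclins 1 and 1 among 17 (0.326), and ion transport 4 and 2 among 28 (0.524). Respiratory chain subunits had 1 and 5 among 43 (0.577), ER chaperones 2 and 3 among 24 (0.866), p53 targets 2 and 1 among 20 (0.375), stem and progenitor genes 3 and 3 among 19 (0.75), with SPI1 at +0.74, and line identity genes 2 and 2 among 8 (0.75). Adjusted over the list alone, counts moved to 10 and 5 for maturing myeloid genes, 6 and 12 for the stress response, 4 and 8 for NRF2 targets, 4 and 5 for interferon genes, 2 and 2 for ER chaperones and 1 and 1 for p53 targets, and stayed the same for the others. Interferon genes had a median of 0.07 and a mean of −0.01, stem and progenitor genes 0.00 and −0.02 and ion transport genes −0.02 and −0.02, all placed higher by camera. Without untreated Kasumi-1 replicate 1, maturing myeloid genes were called (adjusted p = 0.0181), as were glycolysis and hypoxia genes (adjusted p = 0.0234). A filter at FPKM of at least 5 also gave a call to the former (median 0.19, adjusted p = 0.0397), and no filter one to the latter (0.0474).

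**Figure D2:**
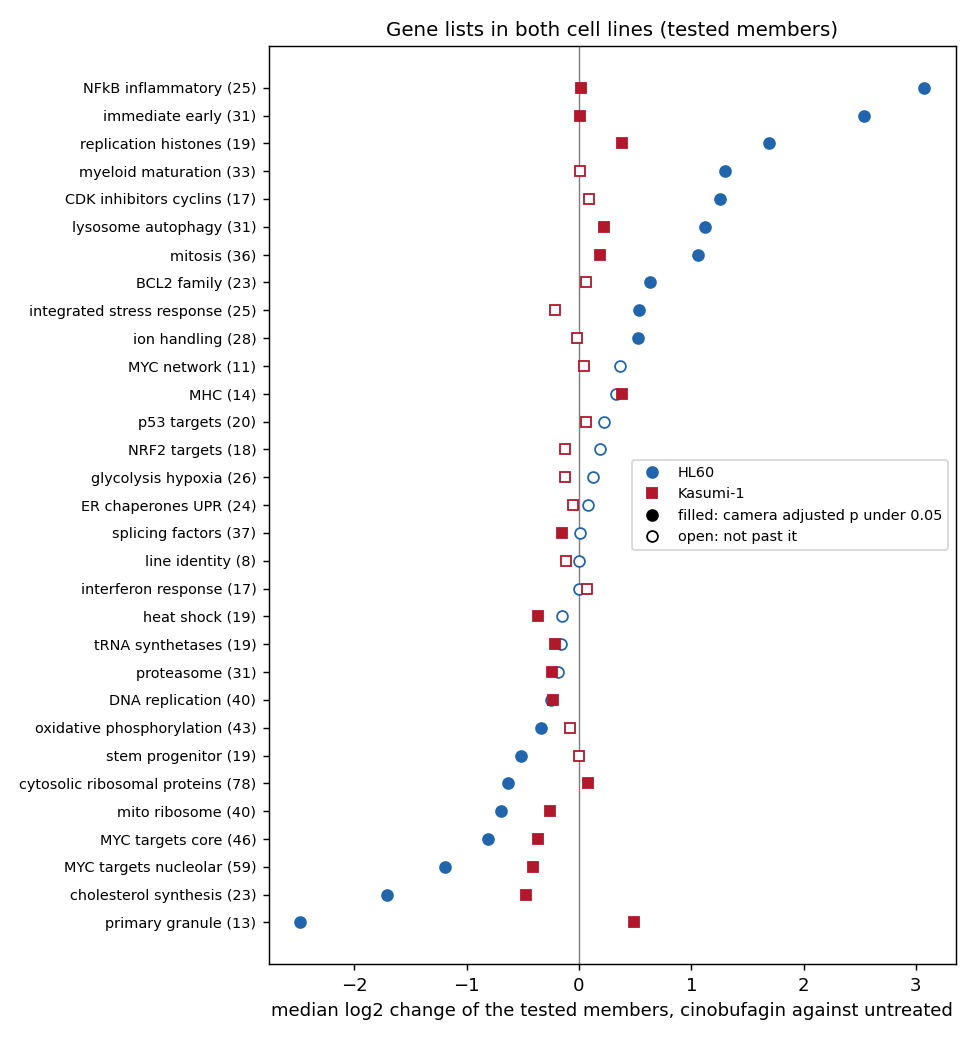
Median log2 change of the tested members of 31 gene lists, with the number of tested members in brackets, in HL60 (blue circles) and Kasumi-1 (red squares), filled where camera's adjusted p with the preset correlation was under 0.05. Inflammatory genes lie at 3.08 in HL60 and 0.02 in Kasumi-1, and primary granule genes at −2.48 and 0.49. The inflammatory list's median level in Kasumi-1 was 0.771 FPKM untreated and 0.541 treated, where the log2(FPKM + 1) scale understates a change.

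The third comparison asked which changes the lines shared and where they differed. Cholesterol genes fell in 23 of 23 cases in HL60 and 17 of 23 in Kasumi-1 (adjusted p = 0.0566 and 0.0635 with an estimated correlation). HMGCS1, MSMO1 and CYP51A1 fell in both lines, together with UCP2, PRG2, PRRT4 and the fatty acid desaturase SCD. CRIP1, HIST1H2BK, SAT1, IL8 and LMNA, which encodes lamin A, rose in both. The 5S copies RN5S4, RN5S6 and RN5S16 were also called higher in both, though the Kasumi-1 calls for RN5S4 and RN5S6 hung on single libraries. LMNA went from 14.6 ± 1.3 to 453 ± 15 FPKM in HL60 and from 2.82 ± 0.15 to 8.10 ± 0.14 in Kasumi-1, and PRG2 from 8130 ± 660 to 1380 ± 210 and from 13.3 ± 2 to 3.41 ± 0.97. The lines have separate untreated libraries, so the contrasts share no control. In both lines, 812 genes rose, against 455.9 for independent lists (Fisher's exact test across genes, p = 2.69e-102), and 1331 fell, against 762.2 (p = 4.49e-173). Rescaling by median ratios gave 1101 shared rises and 1012 shared falls, and quantile normalization 1068 and 1206. Opposite calls were fewer than independent lists give, with 264 genes rising in HL60 and falling in Kasumi-1 (729.5 for independent lists) and 246 the other way (476.3). Of 2653 genes called in both lines 80.8% had the same direction, and 1909 of these 2143 changed more in HL60.

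Across the 12511 genes, which are not independent replicates, log2 changes in the lines correlated with Pearson's r = 0.29 and Spearman's rho = 0.40, and r was 0.39 without short RNAs and repeated symbols. Within a line, changes in replicate 1 and replicate 2 correlated across genes with r = 0.86 in HL60 and 0.39 in Kasumi-1, or 0.98 and 0.78 without short RNAs and repeated symbols. Shared rises numbered 427, 432, 461 and 471 without untreated Kasumi-1 replicates 1 and 2 and treated replicates 1 and 2, and shared falls 726, 703, 773 and 859.

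**Figure D3:**
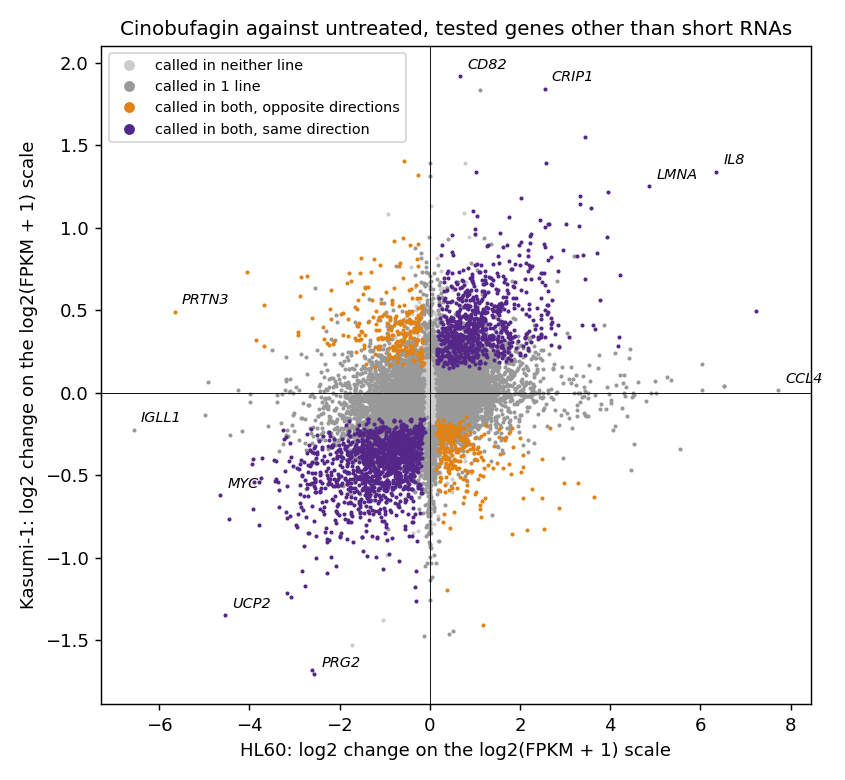
Log2 change with cinobufagin in HL60 (horizontal) and Kasumi-1 (vertical) for 12294 tested genes other than short RNAs, on the log2(FPKM + 1) scale, coloured by the calls in each line. Genes called in both lines lie mostly in the quadrants of equal sign (80.8% of 2653, short RNAs included), and the vertical axis spans a narrower range.

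The change itself differed between the lines for 7897 genes, of which 3761 were higher in Kasumi-1 and 4136 lower (limma, difference of changes, Benjamini-Hochberg). The change of MYC was higher in Kasumi-1 by 4.02 (SE 0.07, adjusted p = 1.53e-06). The largest differences toward Kasumi-1 were those of IGLL1 (6.34), PRTN3 (6.14), MZB1 (4.99), GAL (4.86), DYSFIP1 (4.78) and PLXND1 (4.27). PLXND1, a semaphorin receptor, went from 31.5 ± 0.014 to 0.709 ± 0.031 FPKM in HL60 and from 29.6 ± 1.8 to 29.9 ± 2 in Kasumi-1. Toward HL60 they were those of CCL4 (−7.71), CCL3 (−6.73), CCL4L2 and CCL4L1 (both −6.48, with shared reads), CCL2 (−6.02) and RGS2 (−5.89). MCL1 differed by −3.00 and CDKN1A by −3.61 (adjusted p = 1.23e-05 and 3.02e-06). Of the gene lists, 8 were higher in Kasumi-1 and 10 lower by camera, and 1 and 5 of them held with an estimated correlation: nucleolar MYC targets (median difference 0.90, adjusted p = 0.04 with an estimated correlation) on the Kasumi-1 side, and immediate early, NF-kB, maturing myeloid, mitosis and stress response genes on the HL60 side (0.04, 0.04, 0.04, 0.0451 and 0.0451). In untreated Kasumi-1 the median level was 0.771 FPKM for NF-kB genes and 0.526 for maturing myeloid genes. Changes at such levels are understated by the log2(FPKM + 1) scale, so the size of these 2 differences is uncertain.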

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

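Of the tests weighed here, 3 were chosen only after the result was seen: ribosomal protein changes within replicate numbers, the levels of RNAs without a poly(A) tail, and the exchange of repeated symbols. Results are listed because the change with cinobufagin differed between the lines by limma's test of the difference. No group has enough libraries to test for a single library apart from the rest. Values are the log2 change in Kasumi-1 minus that in HL60, so a positive value is a change that lay higher in Kasumi-1. It held for 3761 genes that were higher in Kasumi-1 and 4136 that were lower. Among the 234 named genes tested and reported here, it held for 214, with 96 higher and 118 lower and adjusted p up to 0.0383 and 0.037. It held for 63.1% of all tested genes. Many named genes were picked from these data for large changes or differences, so a higher share among them is built in. The lines were also grown with different shares of serum, which cannot be told apart from the cell line.

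By camera, 18 lists differed. The median differences were 2.51 for primary granule genes, 1.27 for cholesterol synthesis, 0.90 for nucleolar MYC targets, 0.73 for ribosomal proteins, 0.41 for other MYC targets, 0.40 for the mitochondrial ribosome, 0.32 for stem and progenitor genes and 0.19 for the respiratory chain. On the HL60 side they were −2.89 for NF-kB genes, −2.33 for immediate early genes, −1.42 for histones, −1.12 for maturing myeloid genes, −1.01 for CDK inhibitors and cyclins, −0.87 for mitosis, −0.73 for the stress response, −0.70 for lysosomes, −0.63 for ion transport and −0.62 for the BCL2 family. NF-kB, histone and maturing myeloid genes had median levels of at most 0.771 FPKM in Kasumi-1, where the log2(FPKM + 1) scale understates a change. Of the 18 lists, 12 lost the call with an estimated correlation, with adjusted p from 0.0609 for the BCL2 family to 0.695 for ion transport.

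Genes of the MYC network and its targets differed by the following amounts, with the network first: MYC (4.02), MYCN (−0.45) and MXD1 (−0.73), then SLC29A2 (3.69), SORD (3.24), IMPDH2 (3.02), CAD (2.46), ATIC (2.31), FARSA (2.27), RRP9 (2.2), MYBBP1A (1.65), ODC1 (1.54), PAICS (1.49), NOLC1 (1.11), MRTO4 (1.11), NCL (0.95), CCT3 (0.9) and TERT (0.63). For protein synthesis and mitochondria the genes were MRPL24 (3), RPL12 (2.23), RPS2 (2), MRPL12 (1.8), RPL14 (1.71), MRPL15 (1.28), RPL13A (1.18), MRPL3 (1.05), RPSA (0.99), RPL15 (0.9), RPL23A (0.87), MRPS12 (0.68), MRPS9 (0.47), RPLP1 (0.46) and MRPS7 (0.41), with FARSB (2.17), ATP5D (1.94), NDUFV1 (1.83), QARS (1.72), NDUFB10 (1.35), NDUFB5 (0.86), EPRS (0.58), IARS (0.37), MARS (−1.4) and CARS (−1.41). Sterol and sugar metabolism gave DHCR7 (4.17), LSS (2.05), HMGCS1 (1.95), CYP51A1 (1.75), MSMO1 (1.6), PFKP (1.41), SQLE (1.19), PFKL (0.89), KDM3A (−0.55), PKM2 (−1.28), HK1 (−2.88) and SLC2A3 (−4.26). DNA replication, mitosis and cell cycle control gave POLD2 (1.24), PRIM1 (0.82), CDKN2C (0.28), POLE (−0.27), POLA1 (−0.31), NUF2 (−0.68), CLSPN (−0.76), PBK (−0.77), NUSAP1 (−0.9), CCNE2 (−1.01), RRM2 (−1.08), CDK1 (−1.16), AURKA (−1.51), NDC80 (−1.95), CDKN2A (−1.99), BTG1 (−2.09), CCND3 (−2.98), CDKN1A (−3.61) and BTG2 (−4.19). Histone genes, some of which are near-identical copies, gave HIST1H2BC (−1.12), HIST2H2BE (−1.43), HIST1H2AC (−1.56), HIST2H2AA3 (−1.62), HIST1H2BK (−1.89) and HIST1H2BO (−3.3).

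In inflammation the genes were SOD2 (−0.9), DUSP6 (−1.26), KLF10 (−1.39), NFKBIA (−2.14), JUN (−2.75), RELB (−3.21), NFKB2 (−3.27), DUSP4 (−3.37), MAFF (−3.51), EGR2 (−4.06), FOSB (−4.5), IL1RN (−4.51), IL8 (−5.01), IER3 (−5.85), CCL2 (−6.02), CCL3 (−6.73) and CCL4 (−7.71). Interferon and antigen presentation genes were CD74 (1.79), IFITM1 (1.29), IFITM3 (0.92), TAP2 (0.58), PSMB8 (0.55), IFIT2 (−0.38), HLA-B (−0.68), IRF7 (−0.74), IFIT1 (−0.86), HLA-E (−1.32) and GBP2 (−4.93). Granule, maturation and progenitor genes were PRTN3 (6.14), CTSG (4.21), MPO (3.96), AZU1 (3.55), ELANE (3.29), FLT3 (2.28), CEBPA (2.14), WT1 (2.1), PRSS57 (2.08), CSF3R (2), MYB (1.37), TRH (0.67), SRGN (0.62), KIT (0.39), CD34 (−0.44), POU4F1 (−1.15), FCGR2A (−2.51), FPR1 (−3.37), CD14 (−3.44) and FPR2 (−3.51). Lysosomal genes were CTSB (−0.39), GLA (−0.59), ATP6V0D1 (−1.83), NEU1 (−2.24), SQSTM1 (−2.26) and GABARAPL1 (−3.89). For stress and protein folding the values were CALR (1.86), PDIA4 (1.66), HSP90AB1 (1.13), TALDO1 (0.8), FKBP4 (0.78), HSPA8 (0.66), SYVN1 (−0.24), CBS (−0.28), SEC24D (−0.68), NQO1 (−0.77), CHORDC1 (−0.96), EDEM1 (−0.97), HSPA6 (−0.98), HERPUD1 (−1), SESN2 (−1.22), SLC7A11 (−1.67), VEGFA (−2.31), FTH1 (−2.43), PPP1R15A (−2.98) and HMOX1 (−3.88). Proteasome and splicing genes gave HNRNPA1 (1.12), SNRPA (0.77), PSMD3 (0.23), SF3B2 (0.18), PSMD1 (−0.38), TRA2A (−0.42), PSMD14 (−0.44), PSMD8 (−0.61), CLK4 (−0.61), CLK1 (−1.09) and PSMA1 (−1.11). Survival genes and p53 targets gave FDXR (1.33), BCL2 (1.32), AEN (0.61), BCL2L1 (−0.42), TNFRSF10C (−1.33), CFLAR (−1.53), BMF (−1.66), BIRC3 (−2.37), TNFRSF10B (−2.4), PLK3 (−2.51), MCL1 (−3) and BCL2A1 (−3.65), and ion transport and Na+/K+-ATPase genes FXYD5 (0.76), STK39 (0.61), AKR1B1 (−0.52), ATP2A2 (−0.76), ATP1B1 (−1), ATP1B3 (−1.04), SLC8A1 (−1.71), SLC38A2 (−2), ATP2B1 (−2.25) and SGK1 (−4.11). Genes outside the lists were IGLL1 (6.34), MZB1 (4.99), GAL (4.86), DYSFIP1 (4.78), PLXND1 (4.27), UCP2 (3.2), MFAP4 (1.97), PIWIL4 (1.58), SCD (1.52), CD82 (1.26), PRRT4 (1.02), PRG2 (0.86), CRIP1 (−0.7), ELOVL6 (−0.97), SAT1 (−1.17), MT1G (−1.89), MT1E (−2.59), RN5S4 (−3.1), LMNA (−3.61), RN5S6 (−4.51), RN5S16 (−4.8), RN5S15 (−4.84), RN5S17 (−5.04), RN5S14 (−5.56), RGS2 (−5.89), CCL4L2 (−6.48) and CCL4L1 (−6.48). The 5S and CCL4 copies among them are near-identical, so their values are uncertain. ELOVL6 was near 0 in HL60 (0.249 ± 0.018 to 0.0179 ± 0.025 FPKM), where the log2(FPKM + 1) scale understates a change. By the ratio of means it fell 13.9-fold in HL60 and 2.81-fold in Kasumi-1, so the sign of its difference is uncertain. CD34 and TRH were listed at 0 in all HL60 libraries, so their differences are the Kasumi-1 changes alone.

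Ribosomal protein genes fell in HL60 with a median of −0.63. Of 10000 lists matched on expression and transcript length (median −0.16), 0% lay below it. Those lengths are of the transcript with the longest 3' UTR per gene (list median 1155), which may not be the one expressed. Ribosomal protein genes were also correlated with each other (estimate 0.814), while matched lists held genes drawn separately, so their range is too narrow. Genes of similar annotated length and expression fell less, but transcript length as a cause stays open. Each group holds both replicate numbers, so a difference between the numbers that the groups share cancels by design, and the check on it decides nothing. The smaller fall within a number was −0.59, and replicates of a group differed by at most 0.20. Scaling between libraries stays open too. Median ratios left −0.58, while quantile normalization moved the median to −0.15 and ended the call (camera adjusted p = 0.0579). Quantile normalization gives every library the same distribution of values. It would also shrink a true fall of genes in the highest ranks, such as these (list median 2710 FPKM in untreated HL60), so it cannot decide. An effect of cinobufagin on these mRNAs was not separated from scaling or transcript length and stays open.

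Histone genes and 5S, 7SK, 7SL and U1 RNA stood higher in treated HL60. The pattern was not particular to HL60. In treated Kasumi-1, 7 of 7 RNAs without a poly(A) tail also had higher means, though only 1 was called, and camera called the histone list higher. The explanations below were weighed for HL60 or over all 4 groups. As a candidate explanation, more RNA without a poly(A) tail carried into the treated libraries stays open and was not decided. The 2 such RNAs outside the pattern, RMRP and RPPH1, had higher means in treated HL60, and neither passed limma's test (adjusted p = 0.142 and 0.16). As an explanation, histone reads that follow 7SK within groups stay open too, because the library with more 7SK had the higher histone median in 2 of 4 groups, as unrelated orders also give, so the bound of 2 set beforehand excludes nothing. A change in histone mRNA with cinobufagin was not separated from these and stays open.

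The table holds 45 symbols on more than 1 row (90 rows), and some of these rows changed places between replicate 1 and replicate 2. Of 9 expressed symbols whose rows differed by over 2-fold, exchanging the rows of replicate 2 lowered the difference between replicates for 7 and raised it for KIAA0146 and NBPF9. The summed log2 difference went from 23.34 to 1.49 for ARHGAP27 and from 2.61 to 2.58 for ECSCR, and from 0.58 to 31.33 for KIAA0146 and from 1.61 to 7.26 for NBPF9. As a candidate explanation, rows of repeated symbols joined in a different order for the 2 replicate numbers stay open. No biological explanation was tested.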

How the results depend on the processing

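Alternatives chosen only after the data were seen were the replicate block over both lines and the removal of short RNAs and repeated symbols. Of 5970 checks on 316 named-gene results 5659 gave the same call, 290 lost it, 6 gained it, 15 moved and 0 reversed, and of 1200 checks on 60 list results the numbers were 1100, 50, 21, 27 and 2. Many named genes were picked from these data for large changes or small adjusted p, so a high share of unchanged calls is partly built in. The minimum change of 1.5-fold alone ended 128 named-gene calls. Leaving out 1 library ended the call of 1 of 155 named genes in HL60 (MAX) and of 30 of 134 in Kasumi-1. Depth is known only as a ratio between libraries, so the smallest detectable change of low genes is not known, and the planned count test on recovered reads was not run because gene lengths are not given in the sources used here.

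With a minimum change of 1.5-fold, which by construction asks for larger changes, there were 1969 rises and 2183 falls in HL60, 15 and 11 in Kasumi-1, 8 and 5 in both, and 1471 and 1372 differences, and MYC in Kasumi-1, at −0.62, had an adjusted p of 1. With each line fitted alone, on fewer libraries, Kasumi-1 had 398 rises and 642 falls, of which 256 and 466 were shared with HL60. HL60 fitted alone had 4479 rises and 4656 falls. The median absolute log2 difference between replicates was 0.102 untreated and 0.109 treated in Kasumi-1, against 0.087 and 0.081 in HL60. The spread shared by both lines may therefore understate the error in Kasumi-1. Pearson's r was 0.26 with a pseudocount of 0.1 and 0.39 without short RNAs and repeated symbols, and Spearman's rho 0.35 without a filter and 0.44 at FPKM of at least 5. The cause was not tested.

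With an estimated correlation, 6 lists were higher and 2 lower in HL60, and 0 and 1 in Kasumi-1. Fry, which makes no comparison with other genes, placed 14 lists lower in HL60 and turned the MYC network there, which camera placed higher without calling it, to lower (median 0.36, adjusted p = 0.000175). Quantile normalization left 5 lists higher in Kasumi-1 and turned ribosomal proteins there to −0.03 (adjusted p = 0.491). The cause was not tested.

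Without 1 library, rises in Kasumi-1 ranged from 635 to 1018 and falls from 1019 to 1723, shared rises from 427 to 657 and shared falls from 703 to 1120. Lists higher in Kasumi-1 ranged from 5 (without untreated Kasumi-1 replicate 2) to 8, Pearson's r from 0.22 to 0.3 and Spearman's rho from 0.34 to 0.43. Each of the 4 Kasumi-1 libraries lowered all these gene counts by over 1.5 times. The group then has a lone library, assumed to vary like the other groups, and fewer libraries widen the errors by construction.

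Samples of the same number were treated as sharing only a number, since the labels name no shared batch and there are only 2 numbers. Their deviations from group means correlated across genes at 0.13 to 0.33, and at 0.27 to 0.43 without short RNAs and repeated symbols. With a replicate block within each line there were 4807 rises and 4975 falls in HL60 and 1849 and 2865 in Kasumi-1, and with the block over both lines 1225 shared rises against 812 without it. The NF-kB list lost its call in Kasumi-1 under both blocks (adjusted p = 0.0755 and 0.0617). The cause was not tested.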

Other observations

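The gene families here were chosen after the values were seen. The tests of AU-rich elements were set before their own results were seen, but their hypothesis is drawn from rises seen in these data. In HL60, 10 of 11 tested genes of fatty acid synthesis fell (median −2.02), and in Kasumi-1 8 of 11 fell (median −0.46). FADS2, a fatty acid desaturase, fell from 60.2 ± 2.3 to 3.01 ± 0.22 FPKM in HL60 and from 86.5 ± 8 to 63.7 ± 1.4 in Kasumi-1, and FASN, the fatty acid synthase, fell from 66.3 ± 5.2 to 6.91 ± 0.019 and from 65.8 ± 7 to 38.8 ± 4.5. Metallothioneins, which bind zinc and copper, moved in opposite directions, with 5 of 6 higher in HL60 (median 1.12) and 4 of 6 lower in Kasumi-1 (median −0.72). MT2A went from 77.2 ± 4.5 to 172 ± 18 FPKM in HL60 and from 419 ± 78 to 248 ± 40 in Kasumi-1. Its change was lower in Kasumi-1 (difference −1.89, limma adjusted p = 0.000544). MT1F and MT1H were listed at 0 in Kasumi-1. The fall of MT1G there was lost without untreated replicate 1 (adjusted p = 0.0523), and that of MT1E without untreated replicate 1, untreated replicate 2 or treated replicate 2 (0.0501, 0.0505 and 0.0511). These genes are near-identical copies, so their values are uncertain.

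All 8 tested genes of eosinophil granules and differentiation fell in HL60 (median −1.46). EPX, which encodes eosinophil peroxidase, fell from 351 ± 1 to 21.8 ± 6 FPKM and CLC from 420 ± 43 to 191 ± 20. In Kasumi-1, where PRG3, GATA1 and IL5RA were listed at 0, RNASE2 rose by 0.73 and PRG2 fell by 1.71. Host genes of small nucleolar RNAs fell in 9 of 12 cases in HL60 and 1 rose (median −0.90), with SNHG4 at −2.44, and in 2 of 12 in Kasumi-1 (median −0.03).

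Immediate early and NF-kB genes, many of which encode mRNAs with AU-rich elements, rose in HL60. A hypothesis is that mRNAs with AU-rich elements rose more than others. Genes with the AU-rich nonamer in the 3' UTR (2336 genes) had a median change of 0.18 in HL60, above 100% of 10000 sets of genes without it (median 0.05), matched on 3' UTR length, 3' UTR GC and expression. Of them 46.3% rose, against 35.8% of the 8701 others. Without immediate early and NF-kB genes the median was 0.17. In Kasumi-1 the median was −0.04 against −0.05 in matched sets, above 99.84% of them, a far smaller distance than in HL60. Of the 2336 genes with the nonamer 217 rose and 311 fell in Kasumi-1, and of the 8701 others 944 rose and 1600 fell. Rises there were 9.3% against 10.8%. Altered decay of such mRNAs is an untested hypothesis for these values. A change in their transcription could give the same values, since neither rate was measured. The lines were not compared with each other by a test.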
